A study of Mus musculus with 27 samples.

How the data were processed

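RNA of 27 mouse samples was profiled on Affymetrix arrays, 1 array per sample. Whether a sample held cells of several animals was not stated in the labels. The labels give total RNA taken with Trizol, 100 ng per labelling and a biotin label. The groups were taken from the labels: 6 immortalized neural stem cell lines with mutant p53, 4 with wild-type (WT) p53, 2 cultures of normal neural stem cells (NSCs), 3 pieces of subcutaneous tissue (SubQ) and 12 tumors, 3 from each of lines 1, 31, 59 and 123. Each cell line was measured once.

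The deposited values are log2 expression levels per probe set, made by the authors with RMA; their notes also name GCOS and Affymetrix Expression Console, with no version, order or role. The genome build behind the probe annotation was not given in the sources used here. The values were used as deposited. Cell and tissue arrays looked normalized as 2 sets: of 180 pairs of 1 cell and 1 tissue array none shared an equal value, while the 66 pairs of cell arrays shared 28 to 83 and the 105 pairs of tissue arrays 41 to 626. For this reason, and since the set of arrays goes with cell or tissue, the tests of tumors against their own lines in culture, which had been planned, were not made, and that comparison is a description of values after joint quantile normalization of the arrays involved.

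Of 34760 probe sets, 21640 were listed with 1 gene and were used, 1321 listed with several genes and 11799 without a gene were left out. Genes with several probe sets (954) were represented by the one with the highest mean over the 27 arrays, which gave 19937 genes. Genes measured only by probe sets left out, such as Trp53 and Cdkn1a, were not analysed here. The order of neighbouring genes and the chromosome groups came from the RefSeq annotation of assembly GRCm38.p6, and no coordinate was used.

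Groups were compared with limma 3.58.1 in R 4.3.3, with a linear model per gene and empirical Bayes moderation of the variance. P-values were 2-sided and adjusted by Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05. The comparisons were the 10 immortalized lines against the 2 normal NSCs, the 12 tumors against the 3 SubQ samples, the 6 p53 mutant against the 4 p53 WT lines, and the 4 tumor lines among each other by a moderated F test, followed by each line against the mean of the other 3 lines. The p-values treat the 3 tumors of a line as separate samples. The normal NSCs had 2 arrays, so their spread was pooled with that of the lines. In simulated data with these sample sizes, a log2 change of 1 was called in 71.6% of cases in the first comparison, 73.1% in the second, 88.1% in the third and 59.7% between tumor lines, and a change of 2 in 95.5%, 95.5%, 98.5% and 95.5%. False calls numbered 8, 8, 7 and 8 among 141, 131, 162 and 118 calls in all. The simulated genes were independent, with 1 spread per gene for all groups. Tumors that share a line, correlated genes and the different spread of the SubQ arrays were thus not covered.

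Gene lists (29 lists, 565 genes, 525 of them measured) covered cell types, pathways and gene families, and some genes belong to several lists. They were tested with camera of limma at a preset correlation of 0.01 between genes, with the correlation estimated per list and with fry. Camera compares a list with all other genes, and fry tests whether its genes move on balance in 1 direction. List p-values were adjusted over the 29 lists. Counts of called members are given over all genes and adjusted over the list alone. For tumors against SubQ tissue and for tumors against cultures, list medians were also set against 10000 random lists matched on level. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

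Samples, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. For each comparison of 2 groups the rule named the 10 genes with the largest increases and the 10 with the largest decreases among called genes whose groups did not overlap, without provisional symbols. For each tumor line it named the 4 genes furthest above the other lines. It further named Mdm2, Cdkn2a, Gfap, Nes, Sox2, Olig2, Tubb3, Mki67, Pdgfra and Egfr, and up to 4 called members of each list. In the untested comparison of tumors with cultures the genes named were those in which all 9 tumors lay on 1 side of their own line. Actb, Xist, the Y-linked genes, the odorant and vomeronasal receptors and the genes of runs of neighbouring genes were chosen after their values were seen.

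The alternatives were the mean of all probe sets of a gene, a filter on genes above the median level, eBayes with trend and robust settings, arrays centred on their medians, quantile normalization, an added 2-fold threshold, all 27 arrays in 1 fit, each replicate left out in turn, and the replicate number of the titles as a block. For single comparisons they were the mutant or the WT lines alone, line as a random block, the mean of the 3 tumors of each line, and each tumor line left out. Chosen after seeing the data were the Xist level as a covariate, the list tests with the mutant or the WT lines alone, the matched random lists and the search for runs of neighbouring genes. Groups were also split at random, 100 times each, including the labelled split.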

Results

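Gene expression was measured with 27 Affymetrix arrays, 1 per mouse sample. The cell samples were 10 immortalized neural stem cell lines and 2 cultures of normal neural stem cells (NSCs), the self-renewing cells that give rise to neurons and glia. By their labels, 6 of the 10 lines (lines 3, 28, 31, 59, 95 and 116) carried mutant p53, the tumor suppressor encoded by Trp53, and 4 lines (119, 120, 123 and 331) were p53 wild type (WT). The tissue samples were 12 tumors, 3 from each of lines 1, 31, 59 and 123, and 3 pieces of subcutaneous tissue (SubQ) from severe combined immunodeficient (SCID) mice. Lines 31, 59 and 123 were profiled both in culture and as tumors. Line 1 was profiled here as tumors alone. The median log2 level over all probe sets lay between 7.02 and 7.08 in the immortalized lines, 7.03 and 7.07 in the normal NSCs, 5.47 and 5.57 in the tumors and 5.75 and 5.78 in the SubQ arrays. Nothing in the labels states that arrays of 1 group came from separate cultures or animals beyond calling them biological replicates, so the p-values measure the spread between these samples.

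The first comparison asked how the immortalized lines differed from normal NSCs. Lists of neural stem cell, astrocyte, oligodendrocyte and neuron genes were lower in the 10 lines than in the 2 NSC cultures, and mesenchymal glioma, epithelial-mesenchymal, fibroblast and mural lists were higher. Of the 29 lists camera called 14, and 5 of these with an estimated correlation. These 5 were the astrocyte, mesenchymal glioma, epithelial-mesenchymal, growth factor and receptor, and p53 target lists. Anxa1, a phospholipid-binding protein that restrains inflammation, was higher in the lines (12.47 against 5.86, log2 change 6.61 ± 0.22 SE, limma adjusted p = 2.2e-10). Fabp7, the brain lipid-binding protein of radial glia, fell by 6.88 ± 0.72 SE on the log2 scale, from 13.15 to 6.27 (adjusted p = 1.9e-05). Of 19937 genes, 2992 were called, 1354 higher and 1638 lower in the lines.

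Besides Anxa1, the largest increases were those of S100a6, a calcium-binding protein (6.19 ± 0.14 SE), Ptgs2, the inducible cyclooxygenase (6.13 ± 0.37), Acta2, smooth muscle actin (5.56 ± 0.20), Fgf7, a growth factor of mesenchymal cells (5.41 ± 0.81), and Myof, a membrane repair protein (5.11 ± 0.15). The matrix genes Thbs1, Postn (4.91) and Mgp (4.86) and Met, the receptor of hepatocyte growth factor (4.91 ± 0.30), completed the 10 largest. The largest decreases after Fabp7 were those of Gpm6a, a neuronal membrane glycoprotein (−6.81 ± 0.13 SE), Ptprz1, a receptor phosphatase of glial progenitors (−6.54 ± 0.80), Gria2, an AMPA receptor subunit (−6.33 ± 0.32), and Rtn1, a reticulon of neurons (−5.54 ± 0.14). Rgs7 (−5.50), Gatm (−5.47), Mdga2 (−5.42), Stox2 (−5.31) and Lrrn1 (−5.05) followed. By the rule that named these 20 genes, all 10 lines lay on 1 side of both NSC arrays in each. The lower group lay under the 25th percentile of its gene means in 5 of the 10 increases (6.21 in NSCs; Anxa1, Ptgs2, Myof, Postn and Met) and in 9 of the 10 decreases (6.17 in the lines; all but Fabp7). Such levels were not shown to be above background, so these changes are lower bounds and their order is uncertain.

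**Figure D1:**
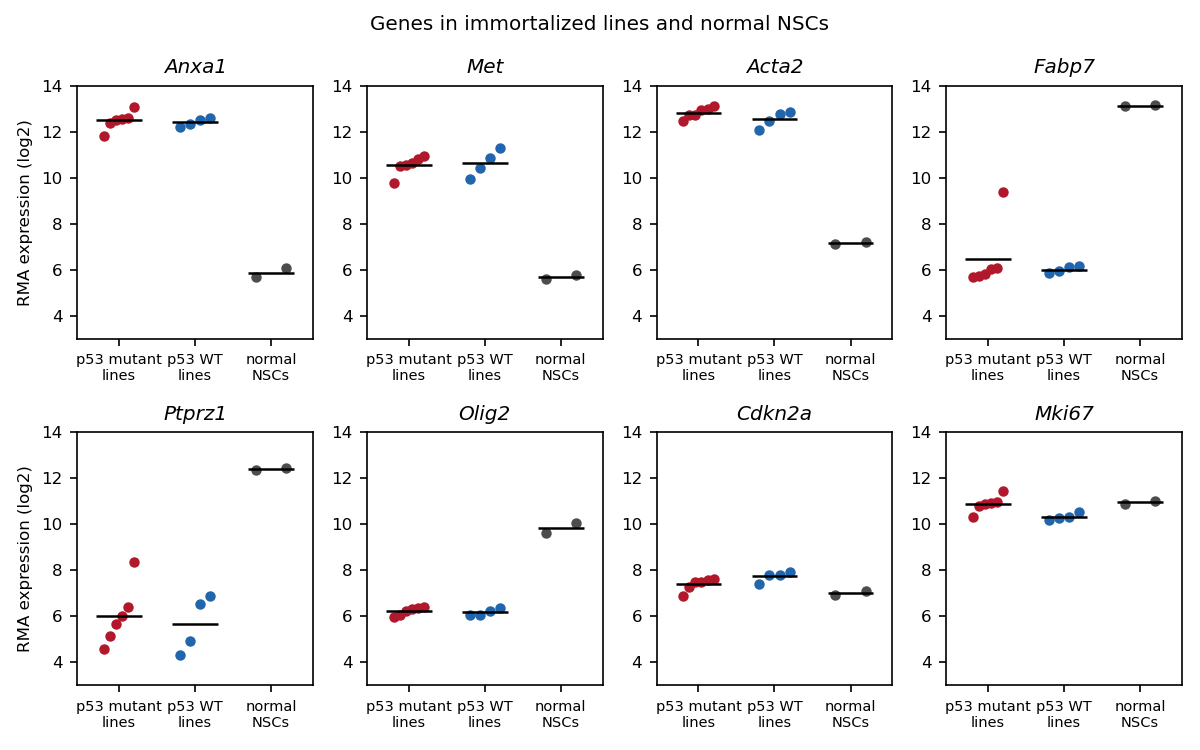
Log2 expression of 8 genes in the 12 cell arrays (y axis, RMA log2), 1 point per array, with the group mean as a bar. The 6 p53 mutant lines, the 4 p53 WT lines and the 2 normal NSCs are drawn in separate columns. Anxa1, Met and Acta2 lie higher in all 10 lines than in both NSC arrays, and Fabp7, Ptprz1 and Olig2 lie lower, while Cdkn2a (0.52) and Mki67 (−0.30) changed by amounts that did not pass the test.

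Neural gene groups fell together. Of the neural stem and progenitor list, 8 of 20 measured members fell and none rose (12 fell adjusted over the list alone; camera adjusted p = 4.9e-06, adjusted p = 0.051 with an estimated correlation). Egfr, the epidermal growth factor receptor, fell by 1.96 ± 0.47, Prom1 by 1.95 and Nr2e1, a nuclear receptor of adult stem cells, by 1.87. The astrocyte list had 13 of 19 members lower and 1 higher (15 and 1 adjusted over the list alone, adjusted p = 3.9e-13, and 0.0049 with an estimated correlation). Its largest decreases were those of Sparcl1 (−4.78), Aldoc (−4.26), Mlc1 (−3.97) and the glutamate transporter gene Slc1a3 (−3.41). In the oligodendrocyte lineage list 8 of 19 fell (9 adjusted over the list alone; adjusted p = 1.4e-06, adjusted p = 0.079 with an estimated correlation). Among them were the transcription factor genes Olig1 (−3.82) and Olig2 (−3.66 ± 0.13, 6.19 in the lines against 9.85) and Lhfpl3 (−3.73). In the neuron list 9 of 22 fell (11 lower and 1 higher adjusted over the list alone; adjusted p = 0.00014, adjusted p = 0.090 with an estimated correlation). Gap43, a growth cone protein, fell by 3.92, Elavl4 by 3.56 and the neurofilament gene Nefm by 2.30. Of the proneural glioma list 6 of 18 fell (10 lower and 1 higher adjusted over the list alone; adjusted p = 2.9e-05, adjusted p = 0.051 with an estimated correlation), including Bcan, a brain proteoglycan (−3.07). Sox2, a stem cell transcription factor, lay at 8.36 in the lines against 9.68 in NSCs (−1.32 ± 0.42 SE, adjusted p = 0.051), and Nes, an intermediate filament of progenitors, changed by −0.75 (adjusted p = 0.50), so neither passed. In the lines Prom1 (5.47), Elavl4 (5.69) and Nefm (5.52) lay under the 25th percentile of genes (6.17), so their falls are lower bounds. Sox2 was called without line 31, 95, 123 or 331 (−1.39 to −1.19).

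Mesenchymal gene groups rose. In the mesenchymal glioma list 16 of 23 rose and none fell (19 rose adjusted over the list alone; adjusted p = 1.4e-18, and 0.0033 with an estimated correlation), including Lox, a collagen cross-linking enzyme (4.72 ± 0.99 SE). In the epithelial-mesenchymal list 10 of 22 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 3.6e-07, and 0.012 with an estimated correlation). Among them were the transcription factor genes Snai2 and Twist1 (2.44) and the contractile gene Tagln (2.60). In NSCs Lox (6.14) and Twist1 (6.19) lay under the 25th percentile of genes (6.21), so their increases are lower bounds. Of the growth factor and receptor list 6 of 25 rose and 1 fell (13 and 2 adjusted over the list alone; adjusted p = 7.1e-06, and 0.020 with an estimated correlation). Met, Pdgfrb (3.29), Csf1, the macrophage growth factor (3.14), and Igf1 (2.17) rose most. Fibroblast genes rose in 6 of 19 cases, such as Cd34 (3.47) and Col1a2 (3.14), and none fell (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.00085, adjusted p = 0.14 with an estimated correlation). In the mural and smooth muscle list 3 of 13 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0014, adjusted p = 0.079 with an estimated correlation). The 3 were Acta2, Pdgfrb and Tagln, which other lists also hold. Immediate early and stress genes rose in 4 of 16 cases, with Atf3 (1.17) and Ddit3 (0.95) higher, and Jun fell by 1.04 (8 and 1 adjusted over the list alone; adjusted p = 0.0031, adjusted p = 0.39 with an estimated correlation).

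3 further lists fell. In the p53 target list 9 of 24 fell and none rose (11 lower and 1 higher adjusted over the list alone; adjusted p = 0.00056, and 0.020 with an estimated correlation). They included Trp53inp1 (−3.36 ± 0.27 SE), Eda2r (−3.33 ± 0.22), the epoxide hydrolase gene Ephx1 (−1.79 ± 0.24) and Zmat3 (−1.58 ± 0.24). In the lines Eda2r (5.82) lay under the 25th percentile of genes (6.17), so its fall is a lower bound. Mdm2, which encodes the ligase that degrades p53, changed by −0.31 (adjusted p = 0.12). With the 4 p53 WT lines alone 8 of these 24 targets fell and 2 rose (camera adjusted p = 0.0012, adjusted p = 0.13 with an estimated correlation), and with the 6 mutant lines alone 8 fell (adjusted p = 0.00041, adjusted p = 0.051 with an estimated correlation). Of the RAS-MAPK output list 7 of 17 fell and 1 rose (9 and 3 adjusted over the list alone; adjusted p = 0.0069, adjusted p = 0.47 with an estimated correlation). They included Etv1 (−3.33), Spry4, Spry2 (−2.53) and Etv5 (−2.17), which the fibroblast growth factor pathway induces. In the cholesterol synthesis list 11 of 15 fell (13 adjusted over the list alone; adjusted p = 1.8e-08, adjusted p = 0.13 with an estimated correlation). Dhcr7 (−1.96), Hmgcs1 (−1.93), Idi1 (−1.51) and Lss (−1.46) fell most.

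The cell cycle list and the remaining lists were not called. In the cell cycle list 1 of 29 genes rose (Tyms, 0.48) and 1 fell (Rrm2, −0.97), with no member higher and 1 lower adjusted over the list alone (adjusted p = 0.95). Mki67, a marker of cycling cells, changed by −0.30 ± 0.27 SE (adjusted p = 0.58). Cdkn2a, which encodes the inhibitors p16 and p19, changed by 0.52 ± 0.21 (adjusted p = 0.12), and the cell cycle inhibitor list had 1 gene higher (Lats2, 1.37) and 1 lower (Cdkn2d, −0.56) of 18 (1 and 1 adjusted over the list alone; adjusted p = 0.51). The hypoxia and glycolysis list had 4 of 18 genes higher, among them P4ha2 (1.89) and Ndrg1 (1.67), and none lower (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.064). It was called without line 31, line 116 or NSC replicate 1 (adjusted p = 0.0497, 0.027 and 0.0059, of a range of 0.0059 to 0.44 over the alternatives). The interferon response list had 2 of 18 higher, Ifit2 and Bst2 (0.79), with 2 adjusted over the list alone (adjusted p = 0.26). Antigen presentation had 2 of 13 higher, B2m (1.18) and Tapbp (0.96), and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.56). Of the imprinted list 3 of 16 fell, Mest (−4.03 ± 1.17 SE), Ndn (−2.96) and Peg3 (−2.60) (4 adjusted over the list alone; adjusted p = 0.19). It was called without line 119 (adjusted p = 0.045, of a range of 0.045 to 0.30). In the lines Ndn (6.10) lay under the 25th percentile of genes (6.17), so its fall is a lower bound. The glial crest list had 2 of 12 lower, led by Ednrb (−4.34), with 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.63). Markers of macrophages (1 higher and 1 lower of 20), endothelium (1 lower of 18), adipocytes (2 lower of 17: Car3, −2.52, and Scd1, −1.40) and skeletal muscle (1 higher of 20: Eno3, 1.71) gave camera adjusted p-values of 0.65, 0.95, 0.69 and 0.69. Adjusted over the list alone these 4 lists had 3 higher and 1 lower, 0 and 0, 0 and 2, and 0 and 0 genes. No gene was called by limma in the keratinocyte, lymphocyte, neutrophil and Hox lists, over all genes or adjusted over the list alone, where 1, 1, 1 and 0 members had an unadjusted p under 0.05, and their camera adjusted p-values were each 0.95. Gfap (0.01), Pdgfra (1.13 ± 1.21 SE) and Tubb3 (1.39 ± 0.49 SE, adjusted p = 0.082) were not called either. Without line 31 Tubb3 was called (1.51), and without line 28 Cdkn2a (0.59).

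The groups did not overlap in 4238 genes, 21.3% of those measured against the 3.03% that chance gives for 10 samples against 2. The count rested on both NSC arrays: 1416 genes were called without NSC replicate 1 and 1402 without replicate 2. Leaving out either NSC array ended the calls of these named genes (log2 change without replicate 1 and without replicate 2): Mgp (4.83 and 4.90), Lox (4.48 and 4.96), Mest (−4.03 and −4.03), Peg3 (−2.54 and −2.66), Egfr (−1.93 and −1.99), Cd34 (3.37 and 3.57), Col1a2 (2.95 and 3.32), Etv1 (−3.38 and −3.28), Igf1 (1.94 and 2.40), Atf3 (1.21 and 1.12), P4ha2 (1.80 and 1.98), Ndrg1 (1.64 and 1.71), Eno3 (1.61 and 1.81), Scd1 (−1.35 and −1.46), Rrm2 (−0.92 and −1.03), Bst2 (0.65 and 0.93), Cdkn2d (−0.50 and −0.62) and Tyms (0.48 and 0.47). The calls of Tagln (2.37), Nr2e1 (−1.75), Idi1 (−1.43), Jun (−0.90) and Tapbp (0.68) ended without replicate 1 alone. The call of Igf1 also ended without line 59, 95, 119 or 331 (2.10 to 2.13), that of Atf3 without line 3, 31, 116, 119, 120 or 123 (1.10 to 1.21) and that of Mest without line 3 (−3.99). An added requirement of at least a 2-fold change left 1204 genes.

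The second comparison set the 12 tumors against the 3 SubQ samples, the site of growth by the labels. Camera called 17 of the 29 lists, among them the cell cycle, mesenchymal glioma, macrophage and hypoxia lists as higher in tumors and the adipocyte, skeletal muscle and keratinocyte lists as lower. With an estimated correlation camera called 0 lists, with 4 at an unadjusted p under 0.05. Lyz2, the lysozyme of macrophages and granulocytes, was 5.26 ± 0.29 SE higher on the log2 scale (11.92 against 6.66, limma adjusted p = 2.5e-10), and Fn1, the matrix protein fibronectin, 5.22 ± 0.33 higher. Trdn, a protein of the calcium release complex of muscle, was 5.34 ± 0.42 lower, at 6.97 in tumors and 12.31 in SubQ tissue. The test called 15256 genes, 6121 higher and 9135 lower in tumors.

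The SubQ arrays had a narrower range of signal than the tumor arrays, which bears on every value of this comparison. The SD over genes was 0.87 to 1.02 in the 3 SubQ arrays and 1.63 to 1.79 in the 12 tumors, and pairs of SubQ arrays correlated at 0.66 to 0.72 across genes against 0.94 to 0.98 for pairs of tumors. Actb, which all cells express, lay at 8.90 ± 0.80 (SD, n = 3) in SubQ tissue and 12.26 ± 0.21 (SD, n = 12) in tumors. Odorant and vomeronasal receptor genes, 1190 genes of sensory neurons, had a median log2 change of −1.24, with median levels of 3.66 in tumors and 4.92 in SubQ tissue, and 1132 of them were called, each lower in tumors. Without these receptors 14124 of 18747 genes were called. The median gene changed by −0.28, by −0.14 with arrays centred on their medians and by −0.11 after quantile normalization, so list medians are given relative to the median of all genes. They are followed by the percentile of the list's median among 10000 random lists matched on tumor level, a comparison chosen after the data were seen. Of the lists called higher, the macrophage list (percentile 97.9) stood above the central 95% of matched lists, the fibroblast list (0.780) stood below it, and the others lay inside it.

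**Figure D2:**
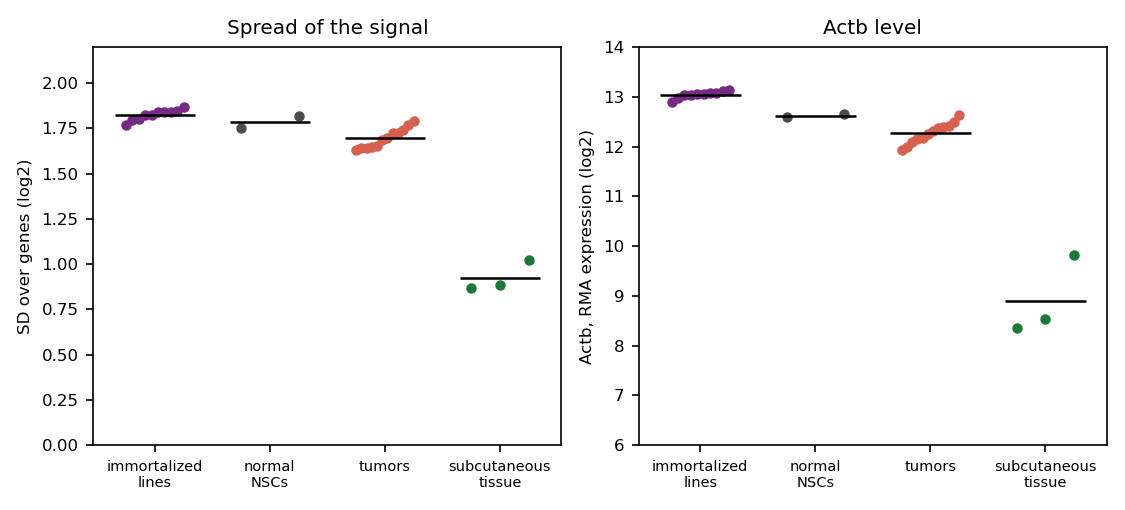
Signal range of the 27 arrays. The left panel plots the SD of the log2 values over 19937 genes per array, and the right panel the RMA log2 level of Actb per array, 1 point per array in 4 classes. The 3 subcutaneous arrays lie at an SD of 0.87 to 1.02, below the 12 tumors at 1.63 to 1.79.

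The other genes with the largest increases were Prdx2, a peroxidase (5.57 ± 0.31 SE), Hnrnpf, a splicing factor (5.16 ± 0.52), Met (5.12 ± 0.89), P4hb, a protein disulfide isomerase (5.06 ± 0.28), Pcna, the sliding clamp of DNA replication (5.04 ± 0.89), Lgals1 (4.83), Plp2 (4.79) and Ppic (4.75). Met varied widely between tumors, from 7.41 to 12.64, and Pcna (SD 3.86, n = 3), Hnrnpf (SD 2.06) and Plp2 (SD 1.74) between SubQ arrays. Without SubQ replicate 1 the increase of Pcna was 2.81. The largest decreases after Trdn were those of Retnla, a secreted protein of adipose tissue and macrophages (−3.98 ± 0.36 SE), Ppp1r3a, a glycogen regulator of muscle (−3.92 ± 0.42), Pof1b (−3.86), the epidermal genes Flg2 (−3.78), Spink5 (−3.66) and Krtdap (−3.65), the RNA gene Rnu6 (−3.71), Cd55 (−3.47) and Skint10 (−3.12). By the rule that named these 20 genes, all 12 tumors lay on 1 side of all 3 SubQ arrays in each. The lower group lay under the 25th percentile of its gene means in 3 of the 10 increases, Prdx2, Met and P4hb (5.38 in SubQ tissue). It did so in 7 of the 10 decreases, all but Trdn, Spink5 and Krtdap (4.75 in tumors). The sizes of these 3 increases are uncertain and are no lower bounds. The SubQ arrays had a narrower range of signal, and Actb also lay lower in them (8.90 against 12.26). The sizes of these 7 decreases are uncertain and are no lower bounds, since receptor genes silent in both tissues also moved by −1.24 in the median.

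Stromal and immune lists were called in both directions by camera on the deposited scale, and no difference between lists was tested. The macrophage and microglia list had 17 of 20 members higher and none lower (also 17 adjusted over the list alone; camera adjusted p = 7.0e-06, adjusted p = 0.31 with an estimated correlation), with the protease gene Ctss at 3.75, Lgmn at 3.50 and Tyrobp at 2.87. Its median lay 2.49 above that of all genes (percentile 97.9). The mesenchymal glioma list had 19 of 23 higher (20 adjusted over the list alone; adjusted p = 5.7e-07, adjusted p = 0.22 with an estimated correlation), including S100a4 (4.68), at a relative median of 2.52 (percentile 94.9). The epithelial-mesenchymal list had 18 of 22 higher (20 adjusted over the list alone; adjusted p = 1.1e-06, adjusted p = 0.12 with an estimated correlation), with Acta2 (4.37), Itgb1 (4.15), Sparc (3.79) and Vim (3.08), at 2.42 (percentile 95.7). Fibroblast genes were higher in 11 and lower in 2 of 19 cases, such as Postn (2.36, and 0.52 without a call after quantile normalization) and Col6a3 (2.33), the same adjusted over the list alone (adjusted p = 0.024, adjusted p = 0.35 with an estimated correlation), at 1.09. Against genes of like level in tumors the list stood low, its median of 0.81 lying at percentile 0.780. After quantile normalization this list was not called (adjusted p = 0.84, of a range of 0.018 to 0.84 over the alternatives). The endothelium list split, with 6 higher, among them Emcn (2.18) and Cdh5 (1.76), and 5 lower of 18 (6 and 4 adjusted over the list alone; adjusted p = 0.33), at 0.31 (percentile 34.8). Mural genes had 3 higher and 5 lower of 13, the same adjusted over the list alone (adjusted p = 0.63), at 0.45 (percentile 20.3), and at −0.35 after quantile normalization. Lymphocyte genes were lower in 12 of 17 cases, such as Cd8a (−1.51), and higher in none, the same adjusted over the list alone (adjusted p = 0.012, adjusted p = 0.35 with an estimated correlation), at −0.52. Their median of −0.80 stood at percentile 59.4 of random lists matched on tumor level, so it was not set apart from genes of like level. The fall of Cd8a lay between the quartiles of the odorant and vomeronasal receptor genes (−1.57 and −0.90). The neutrophil and mast cell list had 12 lower of 17, also adjusted over the list alone (adjusted p = 0.11), at −0.22 (percentile 97.9).

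Genes of the normal tissue were lower in tumors. Adipocyte genes were lower in 16 of 17 cases, the same adjusted over the list alone (adjusted p = 0.0074, adjusted p = 0.35 with an estimated correlation). Fabp4, a fatty acid carrier, lay at −2.91 ± 0.78 SE, the desaturase gene Scd1 at −2.32 and the hormone gene Adipoq at −2.20. Skeletal muscle genes were lower in 15 of 20 cases (Neb, −2.97; Myh4, −2.94) and keratinocyte genes in 14 of 19 (Krt10, −2.67), each the same adjusted over the list alone (adjusted p = 0.041 and 0.027, adjusted p = 0.61 and 0.57 with an estimated correlation). The medians of these 3 lists lay at −1.29, −0.88 and −0.88 relative to all genes, and none of 10000 random lists matched on tumor level had medians as low. The muscle and keratinocyte calls ended without SubQ replicate 2 (adjusted p = 0.11 and 0.059) or without replicate 3 (adjusted p = 0.10 for both), and the muscle call also without replicate 1 of the line 1 tumors (adjusted p = 0.050). Over the alternatives the adjusted p ranged from 0.00010 to 0.11 for muscle and from 0.00010 to 0.10 for keratinocyte genes.

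Groups of growth and metabolism were called higher by camera, but inside the central 95% of random lists matched on tumor level. The cell cycle list had 24 of 29 members higher and 1 lower, the same adjusted over the list alone (adjusted p = 3.5e-06, adjusted p = 0.31 with an estimated correlation), at a relative median of 1.73 (percentile 94.7). Top2a stood at 2.94 (1.09 as the mean of its probe sets), Ccna2 at 2.79 and Mki67 at 1.47 ± 0.25 SE (0.69 without a call after quantile normalization). The cell cycle inhibitor list had 12 higher and 2 lower of 18, the same adjusted over the list alone (adjusted p = 0.0092, adjusted p = 0.31 with an estimated correlation), at 1.37 (percentile 94.9), while Cdkn2a differed by −0.37 (adjusted p = 0.18). Hypoxia and glycolysis genes were higher in 14 of 18 cases, such as Pgk1 (4.47) and Ldha (3.55), the same adjusted over the list alone (adjusted p = 0.0011, adjusted p = 0.35 with an estimated correlation), at 1.55 (percentile 62.4). Cholesterol synthesis had 10 higher, with Sqle at 2.93, and 1 lower of 15, the same adjusted over the list alone (adjusted p = 0.0074, adjusted p = 0.31 with an estimated correlation), at 1.64 (percentile 76.4). RAS-MAPK output had 11 higher, such as Myc (2.72) and Ccnd1 (1.97), and 1 lower of 17 (adjusted p = 0.013, adjusted p = 0.31 with an estimated correlation), at 1.21 (percentile 78.3). The p53 target list had 11 higher, such as Ei24 (2.88) and Mdm2 (2.38 ± 0.21 SE), and 4 lower of 24 (adjusted p = 0.024, adjusted p = 0.22 with an estimated correlation), at 0.78 (percentile 24.1). Interferon response genes were higher in 13 of 18 cases, such as Cxcl10 (2.60) (adjusted p = 0.011, adjusted p = 0.40 with an estimated correlation), at 0.93 (percentile 42.6). The counts of these last 3 lists were the same adjusted over the list alone, and all 3 lost their call after quantile normalization (adjusted p = 0.083, 0.16 and 0.055, the highest values over their alternatives, with 0.0097, 0.018 and 0.0074 the lowest). Growth factor and receptor genes were higher in 11 and lower in 5 of 25 cases (11 and 4 adjusted over the list alone; adjusted p = 0.083), at 0.86 (percentile 69.5), with Pdgfc at 3.20 and Pdgfra, a receptor of platelet-derived growth factor, at 2.21 ± 0.59 SE. Antigen presentation had 5 higher, led by H2-Aa (2.79), and 3 lower of 13 (adjusted p = 0.37), at 0.35 and at −0.22 after quantile normalization, and at percentile 0.410, below the central 95% of matched lists. Immediate early and stress genes had 7 higher and 3 lower of 16 (7 and 2 adjusted over the list alone, camera adjusted p = 0.13), at 0.71 (percentile 39.2). In SubQ tissue Ei24 (5.196), Mdm2 (5.327) and Sqle (5.245) lay under the 25th percentile of genes (5.382), so the sizes of their increases are uncertain.

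Among the neural lists camera called that of the oligodendrocyte lineage on the deposited scale. Oligodendrocyte lineage genes were lower in 13 and higher in 1 of 19 cases, the same adjusted over the list alone (adjusted p = 0.024, adjusted p = 0.35 with an estimated correlation), at −0.41 relative to all genes and at percentile 37.2 of matched random lists. The neural stem (2 higher, 8 lower of 20), astrocyte (4 and 11 of 19), neuron (2 and 11 of 22), proneural glioma (4 and 8 of 18), glial crest (1 and 7 of 12) and imprinted (2 and 6 of 16) lists had camera adjusted p-values of 0.67, 0.22, 0.089, 0.56, 0.22 and 0.90. Adjusted over the list alone the neuron list had 1 higher and 11 lower and the other 5 had equal counts. Their relative medians were −0.02, −0.39, −0.40, −0.12, −0.29 and −0.01 (percentiles 29.4, 2.41, 51.4, 87.5, 20.2 and 21.8), and those of the proneural and imprinted lists turned to 0.04 and 0.28 after quantile normalization. Astrocyte genes were called lower after quantile normalization (adjusted p = 0.037, of a range of 0.037 to 0.36). Hox genes, which pattern the trunk, were lower in 22 of 25 cases, the same adjusted over the list alone (adjusted p = 0.00062, adjusted p = 0.25 with an estimated correlation), such as Hoxa5 (−1.68), at −0.76 (percentile 0.060). Their median change of −1.04 lay between the quartiles of the receptor genes silent in both tissues (−1.57 and −0.90). Of those receptor genes 1132 of 1190 were called lower, so the fall of the Hox list cannot be told apart from that shift. Of the genes named in advance, Nes was higher (1.35 ± 0.49 SE), Gfap (−1.06) and Olig2 (−1.27) were lower, and Sox2 (−0.20) and Tubb3 (0.56) were not called. In SubQ tissue Nes (5.24) lay under the 25th percentile of genes (5.38), so the size of its increase is uncertain. The falls of Gfap and Olig2 lay between the quartiles of the receptor genes silent in both tissues (−1.57 and −0.90). They cannot be told apart from that shift, and Olig2 (4.59) lay under the 25th percentile in tumors (4.75). The calls of Nes (1.03) and Gfap (−0.63) ended without SubQ replicate 1. Egfr was 1.01 higher on the deposited scale and at −0.03 after quantile normalization.

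The groups did not overlap in 10466 genes, 52.5% of those measured against the 0.44% that chance gives for 12 samples against 3. With the 3 tumors of each line averaged to 1 value the test called 13347 genes.

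The third comparison set the 6 p53 mutant lines against the 4 p53 WT lines. Few genes separated them: 4 of 19937 passed the limma test, and the p53 target list had a median difference of 0.01. Prkar2b, a regulatory subunit of protein kinase A, was higher in the mutant lines (10.49 ± 0.21 SD, n = 6, against 9.26 ± 0.23, n = 4; log2 change 1.23 ± 0.13 SE, adjusted p = 0.016). Sema3d, a guidance factor (−2.96 ± 0.37 SE, adjusted p = 0.037), Cpa6, a carboxypeptidase (−1.27 ± 0.15, adjusted p = 0.023), and Thbd, the thrombin receptor thrombomodulin (−0.87 ± 0.09, adjusted p = 0.016), were lower. Mdm2 differed by 0.07 ± 0.11 SE, Cdkn2a by −0.35 ± 0.15, Mki67 by 0.56 ± 0.18, Nes by 1.01 ± 0.43 and Sox2 by 0.83 ± 0.28, with adjusted p-values between 0.42 and 0.91.

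The p53 target list had a median change of 0.01 and a camera adjusted p of 0.79, and none of its 24 measured members was called. Of these members 5 had an unadjusted p under 0.05 in limma, and members went both ways (Zmat3 at 0.52, Trp53inp1 at −0.42). The cell cycle list was called higher in mutant lines (median 0.16, adjusted p = 0.00026, adjusted p = 0.91 with an estimated correlation). Called lower were interferon response (−0.20, adjusted p = 0.0012, 0.73 with an estimated correlation), imprinted genes (−0.57, adjusted p = 0.0017, 0.30 with an estimated correlation), fibroblast (−0.53, adjusted p = 0.022, 0.73 with an estimated correlation) and hypoxia and glycolysis (−0.13, adjusted p = 0.022, 0.73 with an estimated correlation). Single members of these lists were not called over all genes: Mest differed by −2.13 ± 0.84 SE, Dcn by −2.28 ± 0.92, Oasl2 by −1.47 ± 0.51 and Adm by −1.19 ± 0.28. Adjusted over the list alone, 2 interferon response genes, 2 hypoxia genes and 1 immediate early gene passed, all lower, and no member of any other list. The remaining 23 lists had adjusted p-values of 0.23 or more. The fibroblast call ended without line 59, 95, 119 or 331 (adjusted p = 0.063, 0.11, 0.071 and 0.28, of a range of 0.0012 to 0.28). The hypoxia call ended without line 31, 59, 116, 119 or 331 (adjusted p = 0.064, 0.063, 0.054, 0.078 and 0.25, of a range of 0.0012 to 0.25). RAS-MAPK output, antigen presentation and cholesterol synthesis were called without line 116, 123 and 331 in turn (adjusted p = 0.047, 0.021 and 0.019, with highest values of 0.80, 0.59 and 0.98).

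The groups did not overlap in 336 genes, 1.69% of those measured against the 0.952% that chance gives for 6 lines against 4, and 1701 genes had an unadjusted p under 0.05. The 4 calls rested on single lines: limma called 0 genes without line 3, 28, 31 or 119 (1453, 1500, 1319 and 1357 at an unadjusted p under 0.05), 1 without line 59, 2 without line 331, 7 without line 116 or line 120 and 10 without line 123. Calls ended for Prkar2b without line 3, 28, 31, 59, 119 or 331 (1.14 to 1.24), Sema3d without line 3, 28, 31, 59, 95, 116 or 119 (−3.03 to −2.85), Cpa6 without line 3, 28, 31, 95, 119 or 331 (−1.30 to −1.16) and Thbd without line 3, 28, 31, 59, 119 or 331 (−0.87 to −0.81). Xist, the RNA that silences an X chromosome in female cells, lay at 11.16 to 11.97 in 5 of the 6 mutant lines and at 5.53 in line 95, and at 5.93 to 6.24 in the 4 WT lines, so genotype and Xist level were confounded. Set against the same 2 NSC arrays, the 4 p53 WT lines alone called 2390 genes and the 6 mutant lines alone 3084.

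**Figure D3:**
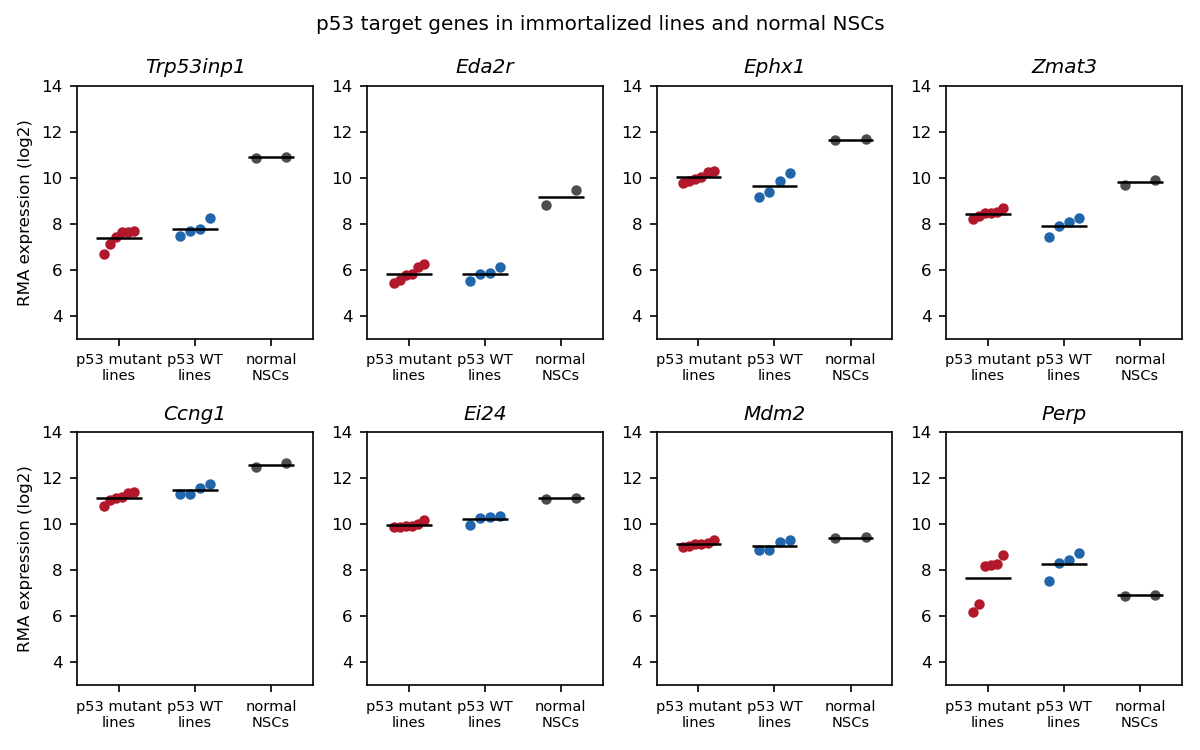
Log2 expression of 8 genes of the p53 target list (y axis, RMA log2) in the 6 p53 mutant lines, the 4 p53 WT lines and the 2 normal NSCs, 1 point per array with the group mean as a bar. Trp53inp1 and Eda2r lie lower in all 10 lines than in both NSC arrays. Mutant and WT lines differ in Trp53inp1 by −0.42, and Eda2r lies at 5.81 and 5.82 in them, under the 25th percentile of genes (6.17).

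The fourth comparison set the tumors of lines 31, 59 and 123 against the same lines in culture. The cell and tissue arrays appeared to have been normalized as separate sets, and tumors also hold host tissue, so no test was made, and the differences describe these 9 tumors and 3 cultures after joint quantile normalization. Genes of macrophages and antigen presentation, and genes of fibroblasts, endothelium and the interferon response, lay higher in tumors, and genes of the cell cycle and of cholesterol synthesis lay lower. Lyz2 lay 7.52 ± 0.16 higher (log2, mean and SD over 3 lines), the class II gene H2-Ea 6.85 ± 0.50, the chemokine gene Ccl12 6.82 ± 0.60 and the chemokine receptor gene Ccr2 6.50 ± 0.80. Alkal1, a ligand of the receptor kinase Alk, lay 3.37 ± 0.55 lower and Thbs1 2.54 ± 0.11 lower. All 10 of the largest increases started from culture levels under the 25th percentile of genes (5.09; Lyz2 at 4.77, Ccr2 at 3.54), and 4 of the 10 largest decreases ended under it in tumors (5.10; Alkal1, Nlrp2, Pantr1 and Bex1). The sizes and the order of these differences are uncertain, since cell and tissue arrays may have different background levels.

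In 3137 genes all 9 tumors lay above their own line and in 4759 below it. Chance gives 1.56% of 19937 genes per direction, but only if a culture array and the tumor arrays of its line differ by chance alone. Cell and tissue arrays appeared to have been normalized separately, so an excess over that share is no test. A difference of at least 2-fold held in 932 of the higher and 472 of the lower genes. The other large increases were those of Ctss (6.42), Lilr4b (6.13), Ms4a6d (6.08), the class II gene H2-Aa, the mannose receptor gene Mrc1 (5.82) and the potassium channel gene Kcnma1 (5.56 ± 3.85 SD, which differed widely between lines). The other large decreases were those of Nrn1 (−2.76), Npr3 (−2.70), Sorbs2 (−2.53), Nlrp2 (−2.52), Tmem171 (−2.52), Fgf7 (−2.52), Pantr1 (−2.44) and Bex1 (−2.35).

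All 20 macrophage genes lay higher in all 9 tumors, with a list median of 3.42, against −0.28 to 0.24 for the central 95% of random lists matched on level. Fibroblast genes lay higher in all 9 tumors in 13 of 19 cases (median 1.58), such as Dcn (4.91), Lum (4.56) and Dpt (4.09). Interferon response genes did so in 13 of 18 cases (1.32), such as Ifit3 (3.52), endothelial genes in 12 of 18 (0.55), such as Emcn (4.34) and Cdh5 (2.37), and antigen presentation genes in 8 of 13 (0.76, 1 lower), with H2-Aa and Cd74 (3.57). Skeletal muscle (1.17, Ttn at 2.97), keratinocyte (0.77, Krtdap at 2.49) and neutrophil and mast cell genes (0.57, Cpa3 at 1.81) had 7 of 20, 2 of 19 and 6 of 17 members above in all 9. The keratinocyte list also had 1 member below in all 9 and the neutrophil list 2. The neutrophil medians per line were 0.41, −0.10 and 0.35 in lines 31, 59 and 123, so line 59 went the other way. Cell cycle genes lay lower in all 9 tumors in 28 of 29 cases (−1.21), with Plk1 at −1.97, Aurkb at −1.92 and Mki67 at −1.11, and cholesterol synthesis genes in 11 of 15 (−0.73), with Idi1 at −1.60. Ccnd1, the D-type cyclin, lay at −1.76. The p53 target list had a median of 0.24 at percentile 99.3 of matched lists, but members went both ways, with 6 of 24 above in all 9 tumors (Trp53inp1 at 1.80, Eda2r at 1.02) and 3 below (Plk2 at −1.10). The epithelial-mesenchymal (0.34), mesenchymal glioma (0.28), imprinted (0.24) and Hox (0.10) lists stood above the central 95% of matched lists as well, also with members on both sides. Epithelial-mesenchymal genes lay above in all 9 in 7 cases, such as Mmp3 (3.56), and below in 2, Cdh2 (−1.47) and Acta2 (−1.12). Mesenchymal glioma genes did so in 5 (Tgfbi at 3.24) and 2 cases, imprinted genes in 5 and 3 (Igf2 at −1.18) and Hox genes in 8 (Hoxa5 at 1.62) and 2. Medians of the other lists were −0.15 for neural stem, −0.08 for astrocyte, −0.17 for oligodendrocyte lineage, −0.16 for neuron, −0.01 for cell cycle inhibitors, −0.05 for growth factors, −0.30 for RAS-MAPK output, −0.05 for proneural glioma, −0.05 for mural, 0.11 for adipocyte, 0.10 for lymphocyte, 0.20 for hypoxia, −0.20 for immediate early and 0.06 for glial crest genes, all inside the central 95% of matched lists. In culture Lum (3.83), Dpt (3.94), Emcn (3.74), Ifit3 (4.82), H2-Aa (4.35), Krtdap (4.49), Cpa3 (3.91), Hoxa5 (3.87) and Eda2r (4.73) lay under the 25th percentile of genes (5.09), so the sizes of their differences are uncertain. Pdgfra lay 1.82 ± 0.76 higher. Sox2 (−0.65 ± 1.47), Nes (−0.98 ± 1.05), Egfr (0.32), Mdm2 (0.24), Olig2 (−0.22), Gfap (−0.14), Tubb3 (−0.06) and Cdkn2a (−0.04) did not lie on 1 side in all 9 tumors.

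**Figure D4:**
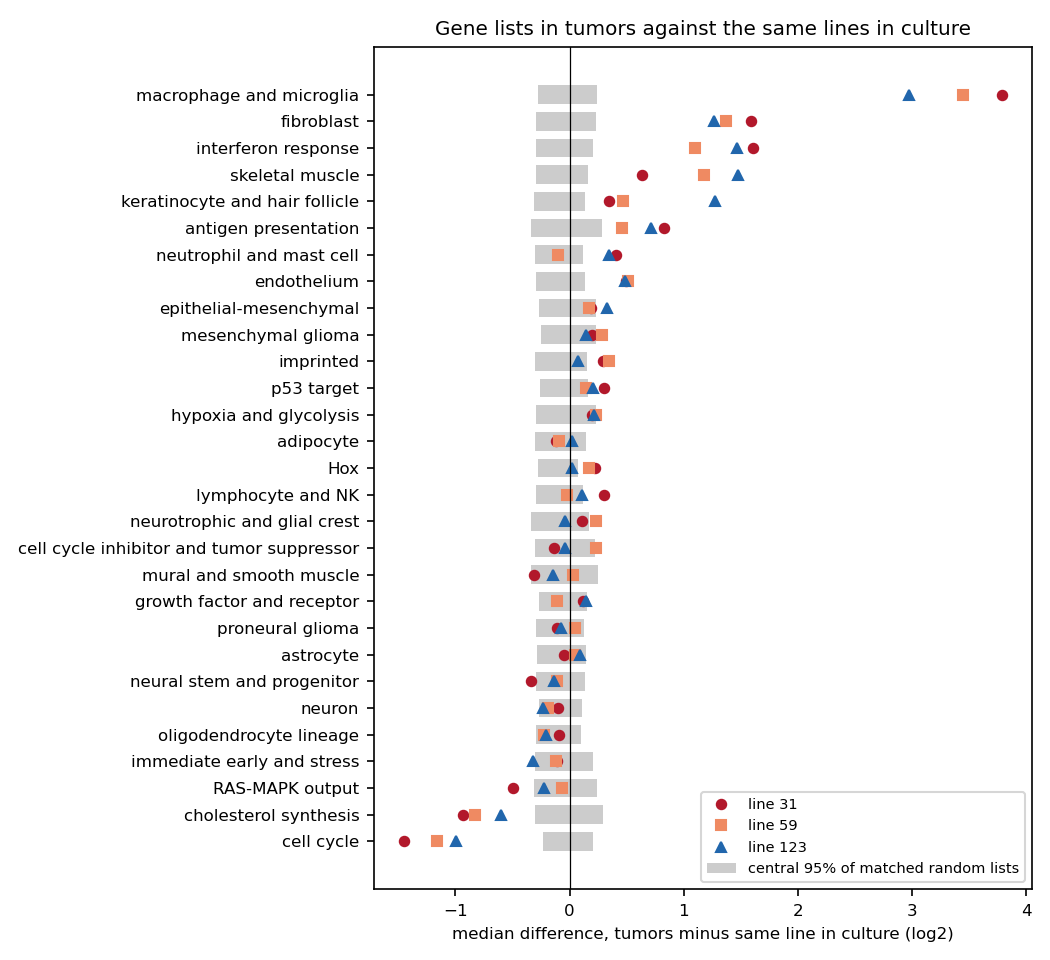
Median log2 difference of each of the 29 gene lists between tumors and the same line in culture (x axis, log2 after joint quantile normalization), 1 point for each of lines 31, 59 and 123. The grey bars span the central 95% of 10000 random lists matched on level. The macrophage list lies at 2.97 to 3.79 and the cell cycle list at −1.45 to −0.99.

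The last comparison asked how the tumors of the 4 lines differed. The tumors of line 1 had the most called genes, and those of line 59 had the highest levels of the neural stem cell genes Sox2 and Nes. Those of line 123 had the highest level of the neuronal gene Stmn2 (10.5, with 8.1 in line 59, 5.7 in line 31 and 5.1 in line 1). The moderated F test of limma called 1010 of 19937 genes, and 4122 had an unadjusted p under 0.05. Against the mean of the other 3 lines, 922 genes were called in line 1 (465 higher), 277 in line 31 (125 higher), 233 in line 59 (150 higher) and 169 in line 123 (125 higher).

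In line 1 the largest differences were those of Tfpi2, a protease inhibitor (4.45 ± 0.23 SE, 11.05 against 6.54 to 6.66 in the other lines, n = 3 each), Caap1, an inhibitor of apoptosis (4.05 ± 0.13), Crhbp, which binds corticotropin-releasing hormone (3.85 ± 0.38), and Tek, the angiopoietin receptor (3.78 ± 0.14). Pdgfra also stood higher in line 1 (10.47 ± 0.56 SD against 7.90 to 8.24; difference 2.38 ± 0.21 SE, F test adjusted p = 0.00037), and Cdkn2a lower (5.14 ± 0.17 SD against 5.91 to 6.13; −0.88 ± 0.12 SE, F test adjusted p = 0.0064). In line 31 the leading genes were Ccdc80 (1.92), Chrdl1 (1.87), Ubd (1.83) and Sema3c (1.76). In line 59 they were the connexin gene Gjc3 (3.51 ± 0.25 SE), Serpina3n (3.07), Itih5 (2.79) and Adh7 (2.74), with Nes 1.78 ± 0.26 and Sox2 1.93 ± 0.36 above the other lines. In line 123 they were Stmn2 (4.20 ± 0.48 SE), the pseudogene Olfr1372-ps1 (3.66), the leptin receptor gene Lepr (3.38 ± 0.27) and Hdx (2.76). Sox2 was lowest in line 1 (−1.61 ± 0.36 SE). Egfr, Gfap, Mdm2, Mki67, Olig2 and Tubb3 did not differ between the lines past the threshold (F test adjusted p between 0.13 and 0.62).

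Among the lists, imprinted genes were called most often, 8 of 16 by the F test, with 5 higher in line 1 and 3 lower in line 31. Macrophage genes were called in 5 of 20 cases, with 5 lower in line 1, whose list mean was 7.90 against 8.21 to 8.78 in the other lines. The neutrophil and mast cell list had 4 of 17 members called, with 4 higher in line 1, the cell cycle inhibitor list 5 of 18, with 4 lower in line 1, and the proneural glioma list 4 of 18. The neural stem, p53 target, growth factor, epithelial-mesenchymal and antigen presentation lists had 3 called genes each, the oligodendrocyte, neuron, cell cycle, RAS-MAPK, mesenchymal glioma and immediate early lists 2 each, and the astrocyte, endothelium, skeletal muscle, interferon, Hox, cholesterol and glial crest lists 1 each. None of the mural, fibroblast, adipocyte, keratinocyte, lymphocyte and hypoxia genes was called, with 3, 6, 2, 6, 0 and 2 members at an unadjusted p under 0.05 in the limma F test. The count of 1010 genes depended on single tumors: 617 were called without line 1 tumor 2, 469 without line 1 tumor 3, 595 without line 31 tumor 1, 1659 without line 31 tumor 3, 668 without line 59 tumor 2, 673 without line 123 tumor 2 and 574 without line 123 tumor 3. An added requirement that 1 line differ at least 2-fold from the mean of the other 3 left 445 genes.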

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

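Of the tests in this part, those with random lists matched on level, with the spread of neural gene changes, of list members with the p53 WT lines alone, with the p53 targets and with the Xist level were chosen only after the result was seen, while the fit with the p53 WT lines alone was planned.

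Single lines stood far from the others of their genotype in 23 of 182 groups of 91 named genes (12.6%), by the gap to the nearest line as a share of the range; chance flags about 1 in 20 groups. Among the 6 p53 mutant lines these were, as log2 levels, line 116 for Fabp7 (9.40 against 5.68 to 6.09 in the others), line 95 for Fgf7 (8.55, others 11.57 to 12.31), Sparcl1 (7.002, others 6.47 to 6.66), Mlc1 (6.93, others 6.23 to 6.41) and Spry4 (8.44, others 6.93 to 7.43), line 59 for Rtn1 (6.25, others 5.81 to 5.92) and Nr2e1 (8.37, others 6.59 to 6.84), line 3 for Gatm (6.28, others 5.22 to 5.61) and Oasl2 (6.88, others 6.43 to 6.59), line 31 for Aldoc (6.71, others 6.91 to 7.02) and line 28 for Lhfpl3 (7.84, others 6.98 to 7.23). Among the 4 p53 WT lines they were line 123 for Mgp (8.21, others 12.22 to 12.49), Gria2 (6.02, others 4.46 to 4.58), Pdgfrb (9.22, others 10.08 to 10.11), B2m (11.81, others 12.34 to 12.44), Ndn (7.56, others 5.98 to 6.20), Ednrb (8.26, others 5.84 to 6.13) and Eno3 (10.69, others 8.42 to 8.53), line 119 for Tyms (9.67, others 9.44 to 9.47) and Peg3 (8.60, others 5.95 to 6.36), line 331 for Mlc1 (5.89, others 6.23 to 6.29) and Snai2 (11.08, others 10.003 to 10.145), and line 120 for Nes (9.17, others 8.11 to 8.24). Line 123 accounts for 7 of these and line 95 for 4. No explanation of these single values was tested.

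The difference between tumors and subcutaneous tissue (SubQ) itself differed between the 4 tumor lines by the limma F test, since all lines share 1 set of SubQ arrays, for Pdgfra (adjusted p = 0.000368), Ccnd1 (0.00407), Cdkn2a (0.00638), Nes (0.00825), H2-Aa (0.0103), Sox2 (0.0141), Cxcl10 (0.022), S100a4 (0.0264) and Ppic (0.0334). Between tumors and cultures, all tumors of line 59 lay above their line for Cdkn2a (mean 0.22) and all tumors of line 31 below it (−0.15); the difference was not tested.

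Most genes were called between tumors and SubQ tissue, 15256 of 19937. Of 100 splits of these arrays 1, the labelled one, gave as many genes, with 6323 the highest of the others. Chance is thus unlikely, but 100 splits cannot exclude it. The narrow signal range of the SubQ arrays is consistent with part of these calls: odorant and vomeronasal receptor genes, silent outside sensory tissue, moved by −1.244 in the median (quartiles −1.57 and −0.90). It does not account for the lower adipocyte, skeletal muscle and keratinocyte genes, whose medians (−1.57, −1.16 and −1.16) lay at percentile 0.0 of random lists matched on tumor level, with 2.5th percentiles of −0.76, −0.22 and −0.60. RNA quality, array batch and cell content of the SubQ pieces and the sex of the host animals stay open and were not tested.

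Neural genes were lower and mesenchymal genes higher in the 10 immortalized lines against 2 NSC cultures. A lower share of neural stem cells in the lines was examined through the spread of the changes of neural genes. The changes of the 38 members of 5 neural lists above a level of 8 in NSCs had an SD of 1.76 (highest other split 0.95, exact permutation p = 0.0152, the smallest that 66 splits can give), and of 1.60 without Fabp7 (highest other 0.85, exact permutation p = 0.0152). These splits cannot decide the question, since genes that end near background fall by amounts that depend on their starting level. Fabp7 went from 13.15 to 6.27 and Olig2 from 9.85 to 6.19, near the 25th percentile of genes in the lines (6.17). For the 13 such neural stem genes taken alone, changes ranged over 6.63 (exact permutation p = 0.0152) but over 1.71 without Fabp7 (exact permutation p = 0.303). A lower share of neural stem cells stays open, as does a replacing cell type that expresses part of the neural genes. Mutation of p53 is argued against as the sole source, since with the p53 WT lines alone 41 of 91 members of these lists were called lower (1 higher) and 33 of 74 members of 4 mesenchymal lists higher (1 lower), 44.8% in these directions. Differences in medium, passage or array batch between lines and NSCs were not tested and may contribute, as may immortalization itself, and the comparison rests on 2 NSC arrays (1416 or 1402 genes called without replicate 1 or 2).

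Few genes separated p53 mutant from WT lines, 4 by limma. Of 100 splits drawn from the 210 possible, 1 (the labelled one) called as many, with 2 the highest of the others. Chance cannot be excluded by so narrow a margin, since the calls rested on single lines. The groups also did not overlap in 1.69% of genes, against 0.952% by chance. With the Xist level as a covariate 23 genes were called and 1 of these 4 kept, Prkar2b (1.23 ± 0.13 SE before, 1.41 ± 0.21 after), while the calls of Cpa6 (−1.27 ± 0.15, then −1.33 ± 0.25), Sema3d (−2.96 ± 0.37, then −2.63 ± 0.61) and Thbd (−0.87 ± 0.09, then −0.75 ± 0.15) ended with a wider SE at a similar size, so genotype and a difference in sex between the lines cannot be told apart for them: 5 of 6 mutant lines and none of the WT lines had high Xist. Loss of p53 function by the mutation is argued against as the sole source for the p53 targets called below NSCs in the mutant lines: the 7 above the 25th percentile of genes in the lines fell by 0.73 to 3.52 but differed by −0.181 in the median between mutant and WT lines (−0.42 to 0.52), and 6 of them were also called lower with the WT lines alone, against the same NSC arrays. A smaller part of the fall, and WT lines that had lost p53 function by another route, could go with the same values and were not tested.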

How the results depend on the processing

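Of the tests in this part, the Xist covariate and the list tests by genotype were chosen only after the result was seen, as alternatives chosen after seeing the data. For lines against NSCs (2992 genes), the replicate number as a block (3032; it does not pair samples), other probe, filter, moderation, centring and normalization settings, all arrays in 1 fit and the mutant or WT lines alone gave 2261 to 3152 genes; an added 2-fold threshold, stricter by construction, gave 1204, and leaving out 1 array gave 1402 to 3170 (under 1.5 times the count apart from NSC replicates 1 and 2, at 1416 and 1402). For tumors against SubQ tissue (15256) other settings, the block (15175), line as a random block, line means and leaving out a line gave 11657 to 15930; the level filter gave 7153 and the 2-fold threshold 8641, both with fewer genes eligible, and leaving out 1 array 14204 to 15249. For p53 mutant against WT lines (4) the level filter gave 1, all 27 arrays in 1 fit 36 and the Xist covariate 23 (the cause was not tested), other settings 3 or 4, and leaving out 1 line 0 to 10 (limma called 0 without line 3, 28, 31 or 119, with 1453, 1500, 1319 and 1357 at an unadjusted p under 0.05). Between tumor lines (1010) other settings and the block (892) gave 892 to 1120, the 2-fold threshold 445, and leaving out 1 tumor 469 to 1659.

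Lists called numbered 14, 17 and 5 in the first 3 comparisons with camera. With estimated correlations, which widen the null, they were 5, 0 and 0, with 10, 4 and 1 at an unadjusted p under 0.05 (with the WT lines alone 1 and the mutant lines alone 3 in the first), with fry 14, 25 and 0, the last with 2 at an unadjusted p under 0.05 (the cause was not tested), and with 1 array left out 14 to 15, 15 to 17 and 3 to 6. The tests of tumors against their own lines were not run, since both sets appeared to have been normalized separately. Genes above the own line in all tumors (3137) and genes below it (4759) numbered 3378 and 4500 with arrays centred. With 1 tumor left out they numbered 3248 to 3416 and 4894 to 5174. These counts cannot fall by construction, since fewer tumors have to lie on 1 side. Of the named genes' values across settings, 2083 of 2229 kept direction and call for lines against NSCs, 3633 of 3674 for tumors against SubQ tissue and 1098 of 1130 between genotypes, and 1419 of 1463 moved by less than the spread between lines for tumors against cultures. Direction reversed for 4 values, all after quantile normalization of tumors and SubQ tissue: B2m (0.92 to −0.43), Dusp1 (0.94 to −0.13), Egfr (1.01 to −0.028) and Zim1 (−0.90 to 0.17); the cause was not tested. The SubQ arrays had a narrower range of signal, with an SD over genes of 0.87 to 1.02 against 1.63 to 1.79 in tumors (signal over background was not measured), and quantile normalization moved the median gene of that comparison from −0.28 to −0.11.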

Other observations

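Of the tests in this part, those of line identity, of Y-linked genes and of runs of neighbouring genes were chosen only after the result was seen.

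Differences between the tumor lines exceeded those of other groupings. With the 4 lines as labelled 1010 genes were called, and 257 at most in the other splits of the 12 tumors into groups of 3. Of 100 splits 1, the labelled one, called as many, so chance is unlikely, but 100 splits cannot exclude it. Tumors were closest to their own line in culture. Across the 1000 genes that varied most between lines 31, 59 and 123 in culture, expression differences correlated at 0.558 with the tumors set to their own line and at 0.233 at most for another assignment (across genes, which are not independent replicates). Expression differences between lines may therefore be kept in the tumors, but 6 assignments allow no p under 0.167.

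Whole chromosomes shifted together. The median shifts of the 19 autosomes, each over the genes used (8992 in all), correlated across chromosomes between the tumors of a line and the same line in culture at 0.526, 0.826 and 0.879 for lines 31, 59 and 123 (mean 0.744, one-sided permutation p = 0.0001, the smallest that 10000 permutations can give), and at 0.201 at most between different lines. Copy number differences carried from culture into tumors are a candidate explanation. No DNA was measured, so the hypothesis rests on expression alone.

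Neighbouring genes were high together in single tumors. In the order of genes of assembly GRCm38.p6, runs of 5 or more genes at least 1 (log2) above the median of the tumors occurred in 8 of 12 tumors and in 0 of 10 immortalized lines set against their own median. The longest held 11 genes, against 4 in 100 shuffled orders per array. All 3 tumors of line 1 had a run with Tek and Mysm1, from Caap1 to Jun in tumors 1 and 3 (8 genes each, medians 3.16 and 3.29) and to Fggy in tumor 2 (9 genes, median 2.96). The 13 genes between and beside Caap1 and Tek had a median difference of 0.914 between line 1 and the other lines, with 7 called: Plaa at 3.32, Ift74 at 3.30, Mysm1 at 3.42 and Jun at 2.88, but Tusc1, on the other side of Caap1, at 0.14. Tumors 1 and 2 of line 31 had a run from Lurap1l to Zdhhc21 with Nfib (5 genes each, medians 2.03 and 1.66). Line 31 also had the highest levels of Nfib (11.53) and Zdhhc21 (10.30) of the 10 lines in culture. Tumor 3 of line 31 lacked this run, with Nfib at 8.58 and Zdhhc21 at 7.62. Runs with Met were found in tumor 3 of line 31 (Tfec to Cftr, 11 genes, median 2.63), tumor 2 of line 59 (Tes to St7, 7 genes, median 3.22) and tumor 1 of line 123 (Tes to Capza2, 6 genes, median 2.78). Focal copy number gains may explain these runs, including the high levels of Caap1 and Tek in line 1 and the high Met of the 3 tumors with a Met run (levels 8.33, 7.41 and 11.97 in line 31, 9.28, 12.02 and 8.88 in line 59, and 12.64, 10.18 and 12.47 in line 123). Tumor 3 of line 123 had high Met without a run of 5 genes (Capza2 at 11.99 and St7 at 9.66, but Tes at 9.34 and Cav2 at 8.39), so its Met level stays open. Tumor 3 of line 31 also had runs of the Ms4a and Ifit families, whose members share sequence and regulation, so a run alone does not show a gain.

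Genes of the X and Y chromosomes described the samples further. NSC replicate 1 had Xist at 11.52 together with the Y-linked gene Eif2s3y at 8.31, and replicate 2 Xist at 5.88 with Eif2s3y at 9.34. Whether replicate 1 held cells of both sexes was not tested. The tumors of lines 31 and 59, whose cultures had Eif2s3y at 4.60 and 4.44, had a mean of 3 Y-linked genes (Eif2s3y, Kdm5d and Uty) 1.071 above SubQ tissue (6.20 ± 0.41 SD, n = 6, against 5.13 ± 0.17, n = 3; exact two-sided permutation p = 0.0119 over 84 splits, the smallest they can give). Cells of male host animals in these tumors are a candidate explanation, but it needs hosts unlike the SubQ animals: the SubQ pieces, the only other tissue of SCID mice here, had Xist at 8.14 to 9.68 and Eif2s3y at 3.74 to 4.45. The tumors of line 123, whose culture had Xist at 5.93, had Xist at 3.77 to 4.56, although macrophage genes lay above culture in them. For the line 123 tumors these values argue against hosts with high Xist like the SubQ animals. Host sex may thus differ between tumors and SubQ tissue, which was not tested. The narrow signal range of the SubQ arrays affects the comparison of Y-linked genes, and the sex of the hosts was not in the labels used.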
